A study of Mus musculus with 8 samples.

How the data were processed

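Expression was measured in 8 samples, 2 biological replicates of each of 4 sorted populations of mouse CD4 single-positive thymocytes. Per the labels, labelled RNA was made from 10 ng of total RNA with a single dye, Cy3. The scanner files were written by Agilent Feature Extraction 10.7.1.1. Per the file headers, the values used are the processed Cy3 intensity of each spot, which the authors' software had background-subtracted and corrected for spatial trends, with no normalization between arrays. The authors also deposited a matrix of linear intensity, scaled so that the 75th percentile of each array is about 1. On each array that matrix was a constant multiple of the processed intensity, and it was used as an alternative.

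Each array held 62976 spots, of which 3671 were controls. Control spots and spots flagged as non-uniform or as outliers were left out, and no spot was saturated (0). Values were put on the log2 scale, the 75th percentile of the array was subtracted, and spots of a probe were averaged. Gene symbols were taken from the RefSeq accession of each probe, because the files carry no column of gene names, and 374 RefSeq accessions had no match. This left 28026 probes with a symbol and 27655 without, for 21154 genes. The array was annotated against an older genome build than the reference used here, so no coordinates are given. For a gene with several probes the probe with the highest mean signal was used. A gene was tested if that probe was well above background, by the flag in the files, on both arrays of at least 1 group, which left 13498 genes. The number of arrays, 2 per group, limits the precision.

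The 4 groups were fitted together in limma 3.58.1 under R 4.3.3 (lmFit and eBayes without a trend), with 4 residual degrees of freedom and a prior of 1.59 degrees of freedom. All 6 pairwise comparisons were tested, with Benjamini-Hochberg adjustment over genes within each at a threshold of 0.05. Where all probes of a gene were below background in a group, its fold is given as a lower bound against the background level, and the fitted value is not printed. Gene lists were tested with camera at a preset correlation between genes of 0.01, with camera at a correlation estimated per list, and with fry, adjusted over the lists of a comparison. A list needed 5 tested genes, which 26 of 27 lists had. The exception was X-inactivation and Y-linked genes.

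The lists held genes of regulatory and conventional T cells, TNF receptor and NF-kB genes, early T cell receptor response genes, pro-apoptotic and survival genes, IL-2 and STAT5 genes, Th1, Th2, Th17 and follicular helper genes, co-inhibitory receptors, maturation and immature thymocyte genes, proliferation, migration receptors, glycolysis, cholesterol synthesis, interferon response and handling stress. Others held markers of B cells, myeloid cells, granulocytes, stroma, red cells and innate-like T cells. The comparisons, lists, tests, alternatives and rule for named genes were fixed before the data were examined. Named genes are the targeted genes, the 10 highest and 10 lowest called differences (5 and 5 for a precursor group against WT Tconv) among genes above background in both groups with separated replicates, the 3 largest lower bounds in each direction, and up to 4 members per list with the smallest adjusted p, plus members whose direction is part of the account.

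Alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, the deposited matrix, no filter on dim probes, only probes above background on all arrays, the mean of the probes of a gene, every probe on its own, an intensity trend, a fit of only the groups compared, the replicate number as a block, a 2-fold minimum, an estimated correlation and leaving out each array. Normexp used the median pixel signal, because the files hold no mean signal. Array weights by group and the removal of Nr4a-TKO replicate 2 with Foxp3-KO replicate 1 were added after the data were seen. Some genes are not reported here. Figures were drawn with matplotlib 3.10.9.

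The procedure was tested on simulated data with the same layout, in which 50 genes were changed at each of 4 sizes in Nr4a-TKO. It recovered 18% of them at 1.5-fold, 62% at 2-fold, 100% at 4-fold and 92% at 8-fold. It called 149 genes in Nr4a-TKO against WT Tconv, 13 of them unchanged, and 0 genes in the 3 comparisons with no change. The list seeded with a change was called, and 0 of 25 unchanged lists were. Genes were simulated independently and with the same spread in all groups. False calls of lists whose genes vary together, or of genes in groups with more spread, were therefore not checked.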

Results

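Gene expression was measured on 8 one-colour microarrays of RNA from mouse thymus. CD4 single-positive thymocytes, the stage at which a thymocyte has kept CD4 and lost CD8, were sorted into 4 populations with 2 biological replicates each and lysed without culture. WT Tconv were wild-type conventional T cells with low CD25, and WT Treg were wild-type regulatory T cells that had Foxp3, the transcription factor of that lineage. Nr4a-TKO preTreg were precursors of regulatory T cells from mice labelled as lacking the Nr4a nuclear receptors, sorted as high in CD25, GITR and Nr4a3. Foxp3-KO preTreg were precursors from mice labelled as Foxp3-deficient, sorted as high in CD25 and positive for a Foxp3 reporter. No wild-type precursor group was measured, so genotype and sort gate changed together in every comparison of a precursor group with a wild-type group. The gates also act on Foxp3, Nr4a3, Il2ra (CD25) and Tnfrsf18 (GITR) directly.

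Of 21154 genes, 13498 were bright enough to test. Between 47.7% and 52.1% of the probes were well above background on an array, and the 75th percentile of signal was 7.97 to 9.20 times the local background. Replicates correlated at r = 0.997 in WT Tconv, 0.990 in WT Treg, 0.990 in Nr4a-TKO and 0.977 in Foxp3-KO across the tested genes, which are not independent replicates. The spread between replicates was 0.18 log2 units in WT Tconv and 0.47 in Foxp3-KO. On the first principal component, with 59.3% of the variance, WT Tconv lay at -81.3 and -80.7, WT Treg at 5.62 and -5.37, and Nr4a-TKO at 94.0 and 75.5. The Foxp3-KO replicates lay apart there, at 21.3 for replicate 1 and -29.2 for replicate 2. All 8 arrays were on 1 slide, with WT Tconv and Nr4a-TKO in its first row and Foxp3-KO and WT Treg in the other, so row and group cannot be told apart where the rows differ. In what follows a difference is log2 ± SE from limma with 2 arrays a group, a gene is called at an adjusted p under 0.05, and a fold against an undetected group is a lower bound. The SE of a gene pools its spread over all 4 groups, so it need not describe the 2 groups compared. The median of a list is that of the log2 differences of its genes. Leading increases and decreases are the largest among called genes above background on all 4 arrays of a comparison, with separated replicates.

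The targeted genes were read first. Foxp3 was at a log2 signal of -3.59 ± 0.28 in WT Tconv (SD, n = 2), 4.86 ± 0.20 in WT Treg, 3.52 ± 0.38 in Nr4a-TKO and 1.86 ± 0.16 in Foxp3-KO. Relative to WT Treg, Foxp3 was lower in Foxp3-KO (-3.00 ± 0.24, adjusted p = 0.0072) and in Nr4a-TKO (-1.34 ± 0.24, adjusted p = 0.0113). It remained higher in Foxp3-KO than in WT Tconv (5.45 ± 0.24, adjusted p = 0.000405). Nr4a2 was higher on the arrays labelled Nr4a-TKO than in WT Treg (2.10 ± 0.20, adjusted p = 0.002), and Nr4a1 was higher there than in WT Tconv (1.01 ± 0.19, adjusted p = 0.0091). Nr4a1 did not pass the test between Nr4a-TKO and WT Treg (0.40 ± 0.19, adjusted p = 0.148), and neither did Nr4a3 (-0.60 ± 0.45, adjusted p = 0.342). The deleted parts of the Nr4a genes and of Foxp3 are not given in the sources used here, so these probes may lie outside them and check no genotype.

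**Figure D1:**
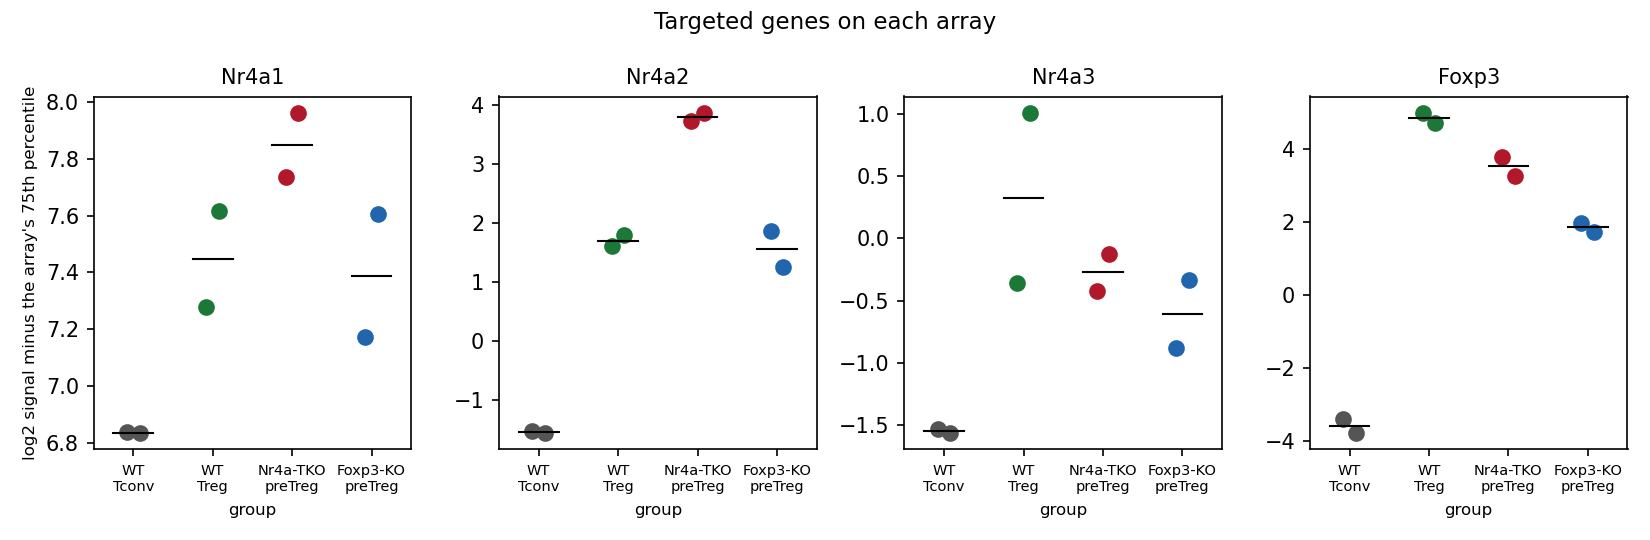
Log2 signal minus the 75th percentile of the array (y axis) for Nr4a1, Nr4a2, Nr4a3 and Foxp3 in the 4 groups (x axis), where each point is an array and each line the mean of 2 arrays. Foxp3 lies between -3.79 and -3.40 on the WT Tconv arrays, between 1.74 and 1.97 on Foxp3-KO, between 3.25 and 3.80 on Nr4a-TKO, and between 4.72 and 5.0 on WT Treg.

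WT Treg against WT Tconv shows what separates regulatory from conventional T cells in the wild-type thymus. Genes that define regulatory T cells were far higher in WT Treg: Foxp3 was 351-fold higher and Lrrc32, which holds latent TGF-beta on the cell surface, 1013-fold. Genes of the TNF receptor and NF-kB pathways were higher as well, and genes of proliferation and of immature thymocytes were lower. With an estimated correlation the TNF receptor and NF-kB call alone held (adjusted p = 0.0482), and the other called lists had adjusted p of up to 0.717. Of 13498 genes, 4774 were called, 1867 higher and 2907 lower, and 1630 of them differed at least 2-fold, 974 higher and 656 lower. With median scaling 1471 were higher and 4234 lower. The leading increases after Lrrc32 (9.98 ± 0.49) and Foxp3 (8.46 ± 0.24) included the chemokine receptor Ccr6 (7.73 ± 0.34), the high-affinity IL-2 receptor chain Il2ra (7.53 ± 0.23), the co-inhibitory receptor Ctla4 (5.85 ± 0.34) and Cd83 (6.90 ± 0.30). With them stood Arhgap20 (6.52 ± 0.20), the G protein regulator Rgs16 (6.25 ± 0.30), Plagl1 (6.11 ± 0.30) and Prr5l (5.83 ± 0.22), with adjusted p of 0.000113 to 0.000423. Penk, the enkephalin precursor, was undetected in WT Tconv and at least 934-fold higher in WT Treg, Ebi3, a subunit of IL-27 and IL-35, at least 240-fold, and the trefoil factor Tff1 at least 220-fold.

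The leading decreases in WT Treg included genes of innate-like lymphocytes. Zbtb16, the transcription factor of innate-like T cells, was at -5.59 ± 0.23, and the NK cell receptor genes Klra16 (-5.34 ± 0.74) and Klrb1a (-4.72 ± 1.13) fell with it. Klra7 was at least 30.4-fold lower and undetected in WT Treg, as were Klra9 (at least 29.8-fold) and Klrc1 (at least 27.1-fold). The chemokine receptor Ccr10 (-5.48 ± 0.11), the scavenger receptor gene Cd163l1 (-5.12 ± 0.93), the adhesion genes Chl1 (-4.74 ± 0.58) and Adgrg5 (-4.54 ± 0.61), Adamts14 (-4.40 ± 0.32), Pdlim4 (-4.34 ± 0.40) and Syt13 (-4.33 ± 0.39) completed that group. The list of innate-like T cell markers as a whole did not pass. Of 16 genes 6 were lower and 2 higher, 6 and 2 adjusted over the list alone (median -0.32, or -0.41 with undetected members at bound, camera adjusted p = 0.392, adjusted p = 0.788 with an estimated correlation).

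Among the lists, regulatory T cell genes were higher. Of 36 genes 26 were higher and 0 lower, 29 and 1 adjusted over the list alone (median 3.03, or 2.76 with undetected members at bound, camera adjusted p = 6.03e-16, adjusted p = 0.351 with an estimated correlation). Beside Foxp3 these were the transcription factor Ikzf2 (5.34 ± 0.15) and the TNF receptor Tnfrsf4 (3.20 ± 0.12). TNF receptor and NF-kB genes moved with them. Of 26 genes 18 were higher and 1 lower, 19 and 1 adjusted over the list alone (median 0.82, camera adjusted p = 5.25e-10, adjusted p = 0.0482 with an estimated correlation). Members were Tnfrsf25 (2.04 ± 0.10), Tnfrsf18 (2.24 ± 0.11), which encodes GITR, and Nfkb2 (1.31 ± 0.08). In the IL-2 and STAT5 list 12 of 20 were higher and 2 lower, 12 and 3 adjusted over the list alone (median 0.83, or 0.59 with undetected members at bound, camera adjusted p = 5.53e-05, adjusted p = 0.180 with an estimated correlation). Cish (2.99 ± 0.11) and Stat5a (1.57 ± 0.11) were higher and Il7r (-2.03 ± 0.25) was lower. Co-inhibitory receptor genes were higher. Of 22 genes 12 were higher and 1 lower, 13 and 1 adjusted over the list alone (median 1.0, camera adjusted p = 3.7e-05, adjusted p = 0.387 with an estimated correlation). Cd200 (2.79 ± 0.08), Cblb (1.23 ± 0.13) and Havcr2 (at least 16.6-fold higher) were members. Of the genes of maturation and thymic exit 11 of 23 were higher and 2 lower, 13 and 2 adjusted over the list alone (median 0.64, or 0.65 with undetected members at bound, camera adjusted p = 0.000176, adjusted p = 0.351 with an estimated correlation). The exit receptor S1pr1 (1.28 ± 0.06) was higher. Early T cell receptor response genes were called higher with members on both sides. Of 30 genes 12 were higher and 4 lower, 13 and 4 adjusted over the list alone (median 0.24, camera adjusted p = 0.0044, adjusted p = 0.387 with an estimated correlation). Dusp4 (5.39 ± 0.19) and Tagap (1.47 ± 0.08) rose and Dusp6 (-1.38 ± 0.07) fell.

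Proliferation genes were lower in WT Treg. Of 37 genes 34 were lower and 0 higher, 36 and 0 adjusted over the list alone (median -1.21, camera adjusted p = 6.03e-16, adjusted p = 0.180 with an estimated correlation). They included the mitotic cyclin Ccnb1 (-1.23 ± 0.06), the ribonucleotide reductase subunit Rrm2 (-1.52 ± 0.08), Kif11 (-1.58 ± 0.09) and Cdc6 (-1.48 ± 0.08). Immature thymocyte genes were lower too. Of 26 genes 15 were lower and 0 higher, 17 and 1 adjusted over the list alone (median -1.10, or -1.16 with undetected members at bound, camera adjusted p = 0.0057, adjusted p = 0.603 with an estimated correlation). Dntt (-2.53 ± 0.36), which adds bases during receptor gene joining, and the receptor Ccr9 (-3.36 ± 0.51) were examples. Migration receptors went both ways. Of 26 genes 10 were higher and 4 lower, 13 and 5 adjusted over the list alone (median 0.37, camera adjusted p = 0.0108, adjusted p = 0.447 with an estimated correlation). Follicular helper genes (6 of 18 were higher and 1 lower, 6 and 2 adjusted over the list alone (median 0.53, or 0.33 with undetected members at bound, camera adjusted p = 0.038, adjusted p = 0.670 with an estimated correlation)) and Th17 genes (5 of 13 were higher and 2 lower, 5 and 2 adjusted over the list alone (median 0.64, or 1.04 with undetected members at bound, camera adjusted p = 0.0396, adjusted p = 0.717 with an estimated correlation)) were called higher. Myeloid markers stood beside these changes. Of 23 genes 9 were higher and 0 lower, 9 and 0 adjusted over the list alone (median 1.76, or 1.83 with undetected members at bound, camera adjusted p = 9.72e-05, adjusted p = 0.632 with an estimated correlation). Ctss (1.33 ± 0.20) and the MHC class II genes H2-Eb1 (2.57 ± 0.53) and H2-Aa (2.65 ± 0.55) were called. The other 14 lists had camera adjusted p of 0.0537 to 0.923, and fry, which asks whether a list moves on balance in a direction, called 13. The TNF receptor and NF-kB call is the sole list call of the 6 comparisons that held with an estimated correlation. Pro-apoptotic genes (camera adjusted p = 0.0537) were called higher with quantile normalization (0.0403) but not with normexp. Cd163l1, H2-Aa, H2-Eb1, Klra7, Klrb1a and Klrc1 lost their calls without some array. The Th17 call ended without WT Treg replicate 2 (adjusted p = 0.0853), and at 0.0957 with quantile normalization, and without the filter on dim probes it ended at 0.175, as did those of early response genes (0.194), follicular helper genes (0.256) and migration receptors (0.175).

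Nr4a-TKO precursors against WT Tconv show how far the precursors of the mice with that label stand from conventional T cells. Regulatory T cell genes were higher on the arrays labelled Nr4a-TKO, with Foxp3 up 139-fold, and the Th1, Th2 and Th17 lists of helper cytokine genes were higher beside them. No list call of this comparison held with an estimated correlation (adjusted p = 0.0719 to 0.501). Genes of conventional T cells and of immature thymocytes were lower. B cell and myeloid markers were higher on the same arrays. In all 6511 genes were called, 2895 higher and 3616 lower, 2626 of them at least 2-fold (1789 higher and 837 lower). The leukotriene B4 receptor Ltb4r1 (8.13 ± 0.84), Lrrc32 (8.02 ± 0.49), Il2ra (7.63 ± 0.23), the IL-33 receptor Il1rl1 (7.49 ± 1.21) and Ctla4 (7.35 ± 0.34) were the leading increases, with adjusted p of 0.000128 to 0.006. From an undetected level in WT Tconv, the chemokine Ccl8 was at least 2107-fold higher, Penk at least 1209-fold and the inhibitory receptor Lilrb4a at least 1057-fold. The leading decreases were Pyroxd2 (-5.49 ± 0.44), the deiminase Padi3 (-4.82 ± 0.35), the transporter Slc16a5 (-4.79 ± 0.30), the thymocyte chemokine receptor Ccr9 (-4.74 ± 0.51) and the AMP deaminase Ampd1 (-4.61 ± 0.65). Mn1, Slc15a1 and Arhgap29 were undetected and at least 23.6-fold, at least 13.9-fold and at least 13.8-fold lower.

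The list of regulatory T cell genes was higher. Of 36 genes 33 were higher and 2 lower, 33 and 2 adjusted over the list alone (median 4.04, or 3.90 with undetected members at bound, camera adjusted p = 2.46e-14, adjusted p = 0.372 with an estimated correlation). Ikzf2 (4.03 ± 0.15) and Tnfrsf4 (2.94 ± 0.12) were among them. TNF receptor and NF-kB genes followed. Of 26 genes 19 were higher and 0 lower, 19 and 0 adjusted over the list alone (median 0.85, camera adjusted p = 5.33e-08, adjusted p = 0.0719 with an estimated correlation). Bcl3 (1.90 ± 0.11), Nfkb2 (1.34 ± 0.08) and Traf1 (1.64 ± 0.10) were members. Of the co-inhibitory receptor genes 15 of 22 were higher and 4 lower, 16 and 4 adjusted over the list alone (median 1.93, camera adjusted p = 3.58e-05, adjusted p = 0.384 with an estimated correlation). Of the IL-2 and STAT5 genes 13 of 20 were higher and 4 lower, 14 and 5 adjusted over the list alone (median 1.06, camera adjusted p = 0.000251, adjusted p = 0.241 with an estimated correlation). Cd200 (3.28 ± 0.08) and Cish (3.12 ± 0.11) were members. Th17 genes were higher. Of 13 genes 12 were higher and 1 lower, 12 and 1 adjusted over the list alone (median 2.93, camera adjusted p = 5.56e-06, adjusted p = 0.384 with an estimated correlation). Batf (2.51 ± 0.18) and Stat3 (1.21 ± 0.10) were examples. For Th2 genes 13 of 22 were higher and 1 lower, 13 and 1 adjusted over the list alone (median 2.88, or 2.77 with undetected members at bound, camera adjusted p = 0.000676, adjusted p = 0.403 with an estimated correlation). The cytokines Il13 (5.20 ± 0.10) and Il5 (at least 124-fold higher) were higher and the receptor Il17rb (-2.25 ± 0.17) was lower. For Th1 genes 11 of 23 were higher and 0 lower, 11 and 0 adjusted over the list alone (median 1.83, or 1.67 with undetected members at bound, camera adjusted p = 0.000491, adjusted p = 0.501 with an estimated correlation). Stat4 (1.53 ± 0.18) and Il12rb1 (1.83 ± 0.28) were called. Follicular helper genes moved the same way. Of 18 genes 13 were higher and 2 lower, 14 and 2 adjusted over the list alone (median 1.92, camera adjusted p = 0.000286, adjusted p = 0.387 with an estimated correlation). Icos (1.70 ± 0.13) and Pdcd1 (2.59 ± 0.24) were among them.

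Early T cell receptor response genes were higher. Of 30 genes 17 were higher and 5 lower, 18 and 6 adjusted over the list alone (median 0.72, camera adjusted p = 0.000368, adjusted p = 0.372 with an estimated correlation). Spry1 (5.84 ± 0.24) and Irf4 (1.60 ± 0.07) were members. Glycolysis genes were higher too. Of 20 genes 12 were higher and 3 lower, 12 and 3 adjusted over the list alone (median 0.53, camera adjusted p = 0.00048, adjusted p = 0.197 with an estimated correlation). Slc16a3 (3.09 ± 0.14) and Tpi1 (2.12 ± 0.10) were examples. Handling stress genes (6 of 15 were higher and 1 lower, 6 and 1 adjusted over the list alone (median 0.47, camera adjusted p = 0.0109, adjusted p = 0.438 with an estimated correlation)) and survival genes (4 of 12 were higher and 1 lower, 4 and 1 adjusted over the list alone (median 0.33, camera adjusted p = 0.0466, adjusted p = 0.372 with an estimated correlation)) were called, the latter with Bcl2 (-1.74 ± 0.18) lower. Genes of conventional T cells were lower. Of 20 genes 15 were lower and 2 higher, 16 and 2 adjusted over the list alone (median -1.49, camera adjusted p = 0.00048, adjusted p = 0.403 with an estimated correlation). Treml2 (-2.25 ± 0.20), Tgfbr3 (-2.57 ± 0.23) and the chromatin organiser Satb1 (-2.49 ± 0.28) were called. Immature thymocyte genes fell too. Of 26 genes 15 were lower and 2 higher, 16 and 2 adjusted over the list alone (median -0.82, camera adjusted p = 0.0011, adjusted p = 0.415 with an estimated correlation). Mns1 (-1.33 ± 0.08) was among them. Proliferation genes did not pass as a list. Of 37 genes 6 were higher and 4 lower, 4 and 4 adjusted over the list alone (median 0.07, mean -0.03 and test direction higher, camera adjusted p = 0.415, adjusted p = 0.833 with an estimated correlation). B cell markers were higher on the same arrays (10 of 11 were higher and 0 lower, 10 and 0 adjusted over the list alone (median 3.84, or 3.49 with undetected members at bound, camera adjusted p = 0.000251, adjusted p = 0.438 with an estimated correlation)), as were myeloid markers (20 of 23 were higher and 1 lower, 20 and 2 adjusted over the list alone (median 3.89, camera adjusted p = 4.26e-06, adjusted p = 0.415 with an estimated correlation)), with Cd74 (3.96 ± 0.44) and C1qa (at least 146-fold higher). The 10 lists without a call, those of granulocyte, stromal and red cell markers among them, had camera adjusted p of 0.0568 to 0.936. Migration receptors, at 0.0568, were called higher with median scaling (0.028) and not with quantile normalization. Fry called 18 of 26 lists. Nr4a1 lost its call without some array. The survival call ended without Nr4a-TKO replicate 1 or WT Tconv replicate 2. It also ended with the mean of a gene's probes (adjusted p = 0.0641) and median scaling (0.0503).

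Foxp3-KO precursors against WT Tconv show which features of the regulatory lineage these precursors had. Regulatory T cell genes were higher, with the transcription factor Ikzf2 up 33.2-fold. TNF receptor and NF-kB genes and co-inhibitory receptor genes were higher as lists, and proliferation genes, 11 of 37 by gene, were lower. No list call here held with an estimated correlation (adjusted p = 0.0573 to 0.474). Myeloid and B cell markers were higher on the same arrays. The test called 3326 genes, 1399 higher and 1927 lower, with 1087 at least 2-fold (821 higher and 266 lower). Lrrc32 (7.99 ± 0.49), Prr5l (6.87 ± 0.22), Arhgap20 (6.56 ± 0.20), the semaphorin receptor Nrp2 (6.45 ± 0.43) and the ribonuclease Ear2 (6.04 ± 0.98) were the leading increases. Undetected in WT Tconv, Penk was at least 527-fold higher, Jchain, which joins secreted immunoglobulins, at least 153-fold, and Pdzk1ip1 at least 81.1-fold. The leading decreases were P4ha2 (-3.29 ± 0.73), the complement regulator Susd4 (-3.13 ± 0.21), Neb (-3.09 ± 0.36), Ccr10 (-3.01 ± 0.11) and Pdlim4 (-2.72 ± 0.40), with adjusted p of 0.000267 to 0.0293. Dmbt1, the Wnt receptor Fzd10 and Fam110b were undetected and at least 6.68-fold, at least 5.18-fold and at least 4.85-fold lower.

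The regulatory T cell list was higher. Of 36 genes 20 were higher and 1 lower, 22 and 2 adjusted over the list alone (median 2.19, or 2.13 with undetected members at bound, camera adjusted p = 3.91e-11, adjusted p = 0.362 with an estimated correlation). Ikzf4 (3.43 ± 0.17), Ikzf2 (5.05 ± 0.15) and Il2ra (5.67 ± 0.23) were members. High CD25 was part of this gate and low CD25 of that of WT Tconv. TNF receptor and NF-kB genes were higher. Of 26 genes 16 were higher and 0 lower, 17 and 0 adjusted over the list alone (median 0.70, camera adjusted p = 4.56e-09, adjusted p = 0.0573 with an estimated correlation). Tnfrsf4 (2.20 ± 0.12) and Tnfrsf18 (1.58 ± 0.11) were examples. Of the co-inhibitory receptor genes 10 of 22 were higher and 1 lower, 10 and 1 adjusted over the list alone (median 1.08, or 1.07 with undetected members at bound, camera adjusted p = 6.46e-05, adjusted p = 0.362 with an estimated correlation). Ctla4 (4.2 ± 0.34) was called. Of the IL-2 and STAT5 genes 8 of 20 were higher and 1 lower, 8 and 2 adjusted over the list alone (median 0.26, camera adjusted p = 0.0015, adjusted p = 0.325 with an estimated correlation). Of the early response genes 11 of 30 were higher and 3 lower, 12 and 3 adjusted over the list alone (median 0.18, camera adjusted p = 0.005, adjusted p = 0.362 with an estimated correlation). Interferon response genes were called higher. Of 28 genes 9 were higher and 1 lower, 9 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.000795, adjusted p = 0.362 with an estimated correlation). Oas1a (0.93 ± 0.11), Ifi44 (1.04 ± 0.17) and Ifit3 (0.68 ± 0.13) were among them. Proliferation genes were lower. Of 37 genes 11 were lower and 0 higher, 13 and 0 adjusted over the list alone (median -0.27, or -0.26 with undetected members at bound, camera adjusted p = 0.000204, adjusted p = 0.362 with an estimated correlation). Kif23 (-1.73 ± 0.17), Ccne1 (-0.69 ± 0.07) and Mcm3 (-0.66 ± 0.07) were members. Th2 genes did not pass. Of 22 genes 6 were lower and 0 higher, 6 and 0 adjusted over the list alone (median -0.09, or -0.27 with undetected members at bound, camera adjusted p = 0.390, adjusted p = 0.754 with an estimated correlation). Il13 (-2.62 ± 0.10) and Il4 (-2.20 ± 0.42) were lower. Myeloid markers stood higher (15 of 23 were higher and 0 lower, 21 and 1 adjusted over the list alone (median 3.19, camera adjusted p = 4.56e-09, adjusted p = 0.362 with an estimated correlation)), with H2-Ab1 (3.75 ± 0.56), and so did B cell markers (4 of 11 were higher and 0 lower, 6 and 0 adjusted over the list alone (median 2.49, camera adjusted p = 0.000528, adjusted p = 0.474 with an estimated correlation)), with Vpreb3 (3.42 ± 0.73).

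Calls that depended on replicate 1 of Foxp3-KO were those of Th17 genes (3 of 13 were higher and 1 lower, 3 and 1 adjusted over the list alone (median 0.82, or 0.47 with undetected members at bound, camera adjusted p = 0.0027, adjusted p = 0.474 with an estimated correlation)), follicular helper genes (7 of 18 were higher and 2 lower, 7 and 3 adjusted over the list alone (median 0.72, camera adjusted p = 0.0085, adjusted p = 0.474 with an estimated correlation)), pro-apoptotic genes (4 of 21 were higher and 2 lower, 6 and 2 adjusted over the list alone (median 0.22, camera adjusted p = 0.0224, adjusted p = 0.325 with an estimated correlation)) and maturation genes (6 of 23 were higher and 1 lower, 6 and 2 adjusted over the list alone (median 0.11, camera adjusted p = 0.0323, adjusted p = 0.458 with an estimated correlation)). Without that array their adjusted p was 0.0794, 0.171, 0.106 and 0.189, in that order, and the maturation call also ended without WT Tconv replicate 2 (0.0876) and in a fit of these groups alone (0.0502). The co-inhibitory call held, with a median of 0.51 without it and 1.69 without replicate 2. The glycolysis call (5 of 20 were higher and 0 lower, 5 and 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.0149, adjusted p = 0.325 with an estimated correlation)) ended without Foxp3-KO replicate 2 (adjusted p = 0.0666). Without the filter on dim probes the calls of IL-2 and STAT5 genes (adjusted p = 0.0870), interferon genes (0.0902), early response genes (0.251), glycolysis genes (0.294), Th17 genes (0.0513), follicular helper genes (0.244), pro-apoptotic genes (0.283) and maturation genes (0.532) ended. Fry called 14 lists, and the 12 lists without a camera call had adjusted p of 0.1001 to 0.917. The count of genes was 470 (335 higher and 135 lower) and 496 (353 and 143) without WT Tconv replicate 1 or 2 and 1285 (764 and 521) in a fit of these groups alone. It was 5026 with median scaling, 1133 higher and 3893 lower, and 2146 (1177 and 969) without the filter on dim probes, and 13 of the 33 genes named here lost their calls without some array (Ear2, Fam110b, Fzd10, H2-Ab1, Ifi44, Ifit3, Il4, Jchain, Neb, Oas1a, P4ha2, Pdlim4 and Vpreb3).

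**Figure D2:**
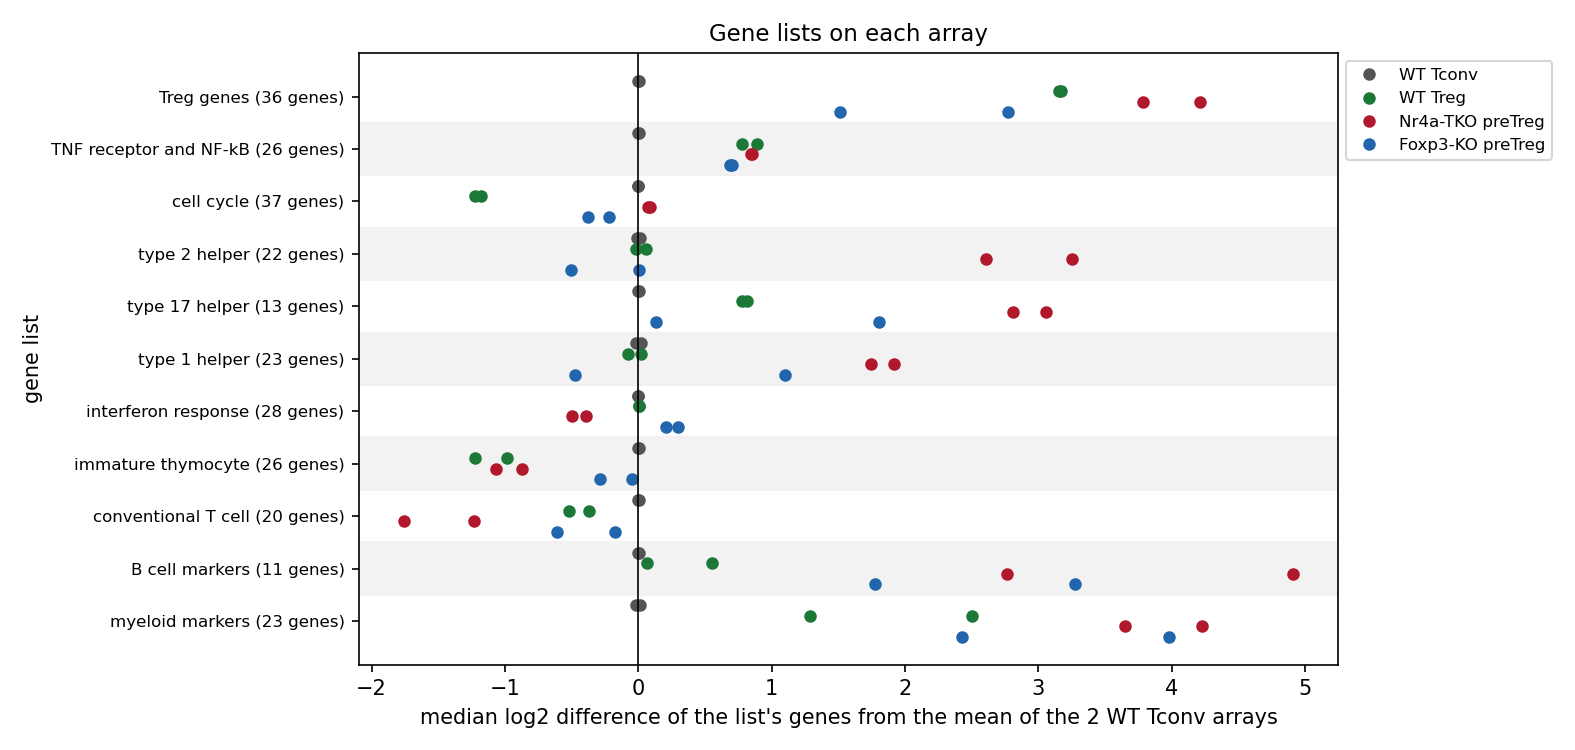
Median log2 difference of each gene list on each array from the mean of the 2 WT Tconv arrays (x axis), for 11 lists (y axis, with the number of tested genes), where each point is an array and colours give the group. The regulatory T cell genes lie at 3.15 and 3.17 on the WT Treg arrays, 3.79 and 4.21 on Nr4a-TKO, and 1.51 and 2.77 on Foxp3-KO, while the Th2 genes lie at 2.61 and 3.25 on Nr4a-TKO and between -0.51 and 0.06 on the other 6 arrays.

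Nr4a-TKO precursors against WT Treg show which genes differ between the precursors of the mice with that label and mature regulatory T cells. Type 2 cytokine genes were far higher on the arrays labelled Nr4a-TKO: Il13 was 314-fold higher and Il4 89.0-fold. Proliferation and glycolysis genes were higher as well, and interferon response genes, maturation genes and genes of conventional T cells were lower, as lists. None of the list calls held with an estimated correlation (adjusted p = 0.204 to 0.698), and the 3 lower calls named also ended without the filter on dim probes. The regulatory T cell list did not pass. Of the tested genes 4776 were called, 2625 higher and 2151 lower, 1760 of them at least 2-fold (1172 higher and 588 lower). With median scaling 2898 were higher and 1418 lower. After Il13 (8.29 ± 0.10) and Il4 (6.48 ± 0.42), the leading increases were in the chemokine Ccl4 (6.56 ± 1.20), granzyme B (Gzmb (6.08 ± 0.97)), the protease inhibitor Slpi (6.04 ± 1.38), the cytokine Il10 (5.82 ± 1.34) and the CGRP precursor Calca (5.69 ± 0.54). The receptor genes Adgrg5 (5.61 ± 0.61) and Ffar2 (5.52 ± 0.30), which binds short-chain fatty acids, and Emp1 (5.22 ± 0.49) followed, with adjusted p of 1.15e-05 to 0.0236 over the 10 genes. Undetected in WT Treg, Ccl8 was at least 1323-fold higher, Ccl3 at least 203-fold and the cytokine Il17a at least 123-fold. The leading decreases were in the cation transporter Slc22a2 (-6.36 ± 0.17), Arhgap20 (-5.92 ± 0.20), Pyroxd2 (-4.56 ± 0.44), Gsta4 (-4.33 ± 0.12) and Cybrd1 (-4.11 ± 0.21). The cilium genes Drc1 (-3.81 ± 0.36) and Ift80 (-3.72 ± 0.15), Galnt14 (-3.70 ± 0.66), the metalloprotease Mmp11 (-3.55 ± 0.24) and the adhesion receptor Selp (-3.52 ± 0.19) were also lower. Lad1, Pla2g4f and C1ql3 were undetected and at least 121-fold, at least 68.3-fold and at least 21.2-fold lower.

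Th2 genes were higher. Of 22 genes 15 were higher and 0 lower, 16 and 0 adjusted over the list alone (median 2.47, or 1.90 with undetected members at bound, camera adjusted p = 5.24e-05, adjusted p = 0.698 with an estimated correlation). Il5 (at least 87.0-fold higher) and Il6 (at least 36.8-fold higher) were examples. For Th17 genes 8 of 13 were higher and 0 lower, 9 and 1 adjusted over the list alone (median 1.54, camera adjusted p = 0.0038, adjusted p = 0.698 with an estimated correlation). Batf (1.54 ± 0.18) and Il17re (at least 15.7-fold higher) were called. For Th1 genes 10 of 23 were higher and 1 lower, 10 and 1 adjusted over the list alone (median 1.69, camera adjusted p = 0.011, adjusted p = 0.698 with an estimated correlation). Runx3 (1.53 ± 0.21) and Il12rb1 (1.91 ± 0.28) were among them. B cell markers were higher on the same arrays (8 of 11 were higher and 0 lower, 8 and 0 adjusted over the list alone (median 3.15, or 2.75 with undetected members at bound, camera adjusted p = 0.005, adjusted p = 0.698 with an estimated correlation)), as were myeloid markers (6 of 23 were higher and 1 lower, 0 and 0 adjusted over the list alone (median 2.03, or 2.05 with undetected members at bound, camera adjusted p = 0.011, adjusted p = 0.698 with an estimated correlation)), which passed the test as a list and not gene by gene within it. Proliferation genes were higher. Of 37 genes 34 were higher and 0 lower, 34 and 0 adjusted over the list alone (median 1.21, camera adjusted p = 3.2e-17, adjusted p = 0.204 with an estimated correlation). Ccnb1 (1.54 ± 0.06), Rrm2 (1.89 ± 0.08), Ccnb2 (1.43 ± 0.08) and Cdk1 (1.52 ± 0.09) were members. Glycolysis genes were higher. Of 20 genes 13 were higher and 3 lower, 14 and 4 adjusted over the list alone (median 0.69, camera adjusted p = 0.000951, adjusted p = 0.204 with an estimated correlation). Pgam1 (1.17 ± 0.06), Aldoa (1.45 ± 0.09) and Pgk1 (0.97 ± 0.07) were examples. Early T cell receptor response genes (15 of 30 were higher and 6 lower, 16 and 6 adjusted over the list alone (median 0.51, camera adjusted p = 0.0236, adjusted p = 0.698 with an estimated correlation)) and handling stress genes (4 of 15 were higher and 0 lower, 2 and 0 adjusted over the list alone (median 0.67, camera adjusted p = 0.0236, adjusted p = 0.698 with an estimated correlation)) were called higher, with Irf4 (1.39 ± 0.07) up, Myc (-0.90 ± 0.09) down and Atf3 (3.69 ± 0.41) up.

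Interferon response genes were lower. Of 28 genes 13 were lower and 5 higher, 14 and 5 adjusted over the list alone (median -0.37, camera adjusted p = 0.0134, adjusted p = 0.698 with an estimated correlation). Oasl2 (-1.54 ± 0.11), Ifit2 (-1.08 ± 0.10), Ifit3 (-1.21 ± 0.13) and Irf9 (-0.72 ± 0.08) were called. Maturation and exit genes were lower. Of 23 genes 11 were lower and 2 higher, 12 and 6 adjusted over the list alone (median -0.67, camera adjusted p = 0.0134, adjusted p = 0.698 with an estimated correlation). S1pr1 (-2.06 ± 0.06), its regulator Klf2 (-1.21 ± 0.07) and Foxo1 (-1.19 ± 0.11) were among them. Genes of conventional T cells were lower. Of 20 genes 12 were lower and 4 higher, 13 and 5 adjusted over the list alone (median -0.96, camera adjusted p = 0.0236, adjusted p = 0.698 with an estimated correlation). Klf3 (-1.61 ± 0.12) and Dapl1 (-2.58 ± 0.28) were members. The regulatory T cell genes went both ways. Of 36 genes 8 were lower and 8 higher, 10 and 11 adjusted over the list alone (median -0.06, mean 0.61 and test direction lower, camera adjusted p = 0.933, adjusted p = 0.982 with an estimated correlation). Icos (1.77 ± 0.13) was higher and Ikzf4 (-2.96 ± 0.17), Ecm1 (-1.45 ± 0.13), Gpr83 (-1.94 ± 0.23) and Foxp3 (-1.34 ± 0.24) were lower. TNF receptor and NF-kB genes did not pass (camera adjusted p = 0.971). The 14 lists without a call had camera adjusted p of 0.0509 to 0.971, and fry called 9. Co-inhibitory, follicular helper and innate-like genes were called higher without the filter on dim probes (adjusted p = 0.0013 to 0.0032). A fit of these groups alone also called them (0.0056 to 0.0393), but quantile and median scaling did not. Ccl3, Ccl4, Foxp3, Galnt14, Il10 and Slpi lost their calls without some array. Leaving out Nr4a-TKO replicate 1 ended the calls of stress and conventional T cell genes. Leaving out WT Treg replicate 1 ended those of stress and early response genes. Without the filter on dim probes the lower calls of interferon genes (adjusted p = 0.0960), maturation genes (0.0960) and conventional T cell genes (0.133) ended, leaving 12 lists higher and 0 lower by camera. With only probes above background on all arrays the Th17 call (adjusted p = 0.0856, median 0.29 over 7 genes) and the stress call (0.0571) ended, the early response call ended with median scaling (0.0513), and the maturation call ended without Nr4a-TKO replicate 2 and Foxp3-KO replicate 1 together (0.114), a choice made after the data were seen.

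Foxp3-KO precursors against WT Treg show which genes differ between these precursors and mature regulatory T cells. Proliferation and immature thymocyte genes were higher in Foxp3-KO, and regulatory T cell genes, IL-2 and STAT5 genes and TNF receptor and NF-kB genes were lower, as lists. None of these calls held with an estimated correlation (adjusted p = 0.216 to 0.490). Foxp3 was 8.03-fold lower and Zbtb16, the transcription factor of innate-like T cells, 12.8-fold higher. The test called 865 genes, 470 higher and 395 lower, 375 of them at least 2-fold (214 higher and 161 lower). After Klra16 (4.88 ± 0.74), Syt13 (3.81 ± 0.39) and Zbtb16 (3.68 ± 0.23), the leading increases were in Chl1 (3.11 ± 0.58), the steroid dehydrogenase Akr1c18 (3.07 ± 0.34), Adgrg5 (3.06 ± 0.61) and Upb1 (2.77 ± 0.10). Cox6a2 (2.77 ± 0.16), the receptor gene Adgrg3 (2.56 ± 0.32) and Endou (2.56 ± 0.44) followed, with adjusted p of 0.0013 to 0.0486 over the 10 genes. The NK receptor genes Klra7, Klra4 and Klra9 were undetected in WT Treg and at least 31.1-fold, at least 19.3-fold and at least 17.5-fold higher. Foxp3 (-3.00 ± 0.24) led the decreases, followed by Flicr (-2.57 ± 0.47), a non-coding RNA gene beside Foxp3, Ebi3 (-2.51 ± 0.48), Neb (-2.48 ± 0.36), Plagl1 (-2.36 ± 0.30) and Susd4 (-2.34 ± 0.21). The laminin chain Lama5 (-2.33 ± 0.34), Mtmr7 (-2.26 ± 0.44), the G protein regulator Rgs9 (-2.26 ± 0.44) and Cavin1 (-2.19 ± 0.31) were lower too. Tlcd5, Magi1 and the potassium channel Kcnj15 were undetected and at least 6.59-fold, at least 6.55-fold and at least 6.03-fold lower.

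Proliferation genes were higher in Foxp3-KO. Of 37 genes 27 were higher and 0 lower, 33 and 0 adjusted over the list alone (median 0.96, or 0.99 with undetected members at bound, camera adjusted p = 3.91e-24, adjusted p = 0.216 with an estimated correlation). Ccnb1 (1.17 ± 0.06), Rrm2 (1.28 ± 0.08), Aurka (1.15 ± 0.08) and Cdk1 (1.24 ± 0.09) were examples. For immature thymocyte genes 4 of 26 were higher and 0 lower, 7 and 0 adjusted over the list alone (median 0.87, camera adjusted p = 5.12e-05, adjusted p = 0.490 with an estimated correlation). Cd24a (1.81 ± 0.19), Dntt (1.94 ± 0.36) and Cd8a (1.85 ± 0.35) were called. Glycolysis genes (4 of 20 were higher and 0 lower, 8 and 0 adjusted over the list alone (median 0.14, camera adjusted p = 0.0101, adjusted p = 0.224 with an estimated correlation)), such as Pgk1 (0.54 ± 0.07) and Eno1 (0.48 ± 0.08), and interferon response genes (2 of 28 were higher and 0 lower, 2 and 0 adjusted over the list alone (median 0.19, camera adjusted p = 0.0047, adjusted p = 0.587 with an estimated correlation)), such as Gbp2 (0.80 ± 0.10), were higher. The regulatory T cell list was lower. Of 36 genes 9 were lower and 0 higher, 19 and 0 adjusted over the list alone (median -1.21, camera adjusted p = 8.95e-11, adjusted p = 0.490 with an estimated correlation). Izumo1r (-0.97 ± 0.09), which encodes folate receptor 4, and Gpr83 (-2.04 ± 0.23) were among them. The IL-2 and STAT5 genes followed. Of 20 genes 4 were lower and 0 higher, 10 and 1 adjusted over the list alone (median -0.40, or -0.38 with undetected members at bound, camera adjusted p = 0.000328, adjusted p = 0.224 with an estimated correlation). Cish (-1.08 ± 0.11), Il2ra (-1.86 ± 0.23) and Jak3 (-0.56 ± 0.08) were members. For TNF receptor and NF-kB genes 5 of 26 were lower and 0 higher, 7 and 0 adjusted over the list alone (median -0.16, camera adjusted p = 0.002, adjusted p = 0.216 with an estimated correlation). Tnfrsf25 (-0.82 ± 0.10), Tnfrsf4 (-1.0 ± 0.12) and Traf1 (-0.81 ± 0.10) were examples. Maturation genes were lower (4 of 23 were lower and 0 higher, 6 and 0 adjusted over the list alone (median -0.29, camera adjusted p = 0.0024, adjusted p = 0.490 with an estimated correlation)), and so were migration receptors (4 of 26 were lower and 1 higher, 6 and 2 adjusted over the list alone (median -0.31, camera adjusted p = 0.0283, adjusted p = 0.617 with an estimated correlation)), with Ccr6 (-2.09 ± 0.34) lower and Ccr10 (2.47 ± 0.11) higher. Helper genes did not pass. For Th2 genes 0 of 22 were lower and 1 higher, 3 and 4 adjusted over the list alone (median -0.32, or -0.44 with undetected members at bound, camera adjusted p = 0.610, adjusted p = 0.911 with an estimated correlation). For Th1 genes 0 of 23 were higher and 0 lower, 0 and 0 adjusted over the list alone (median 0.07, or 0.21 with undetected members at bound, camera adjusted p = 0.610, adjusted p = 0.911 with an estimated correlation). For Th17 genes 2 of 13 were lower and 1 higher, 4 and 1 adjusted over the list alone (median -0.05, or -0.06 with undetected members at bound, mean 0.25 and test direction lower, camera adjusted p = 0.707, adjusted p = 0.911 with an estimated correlation). Without Foxp3-KO replicate 1 the Th1, Th2 and Th17 lists were called lower (adjusted p = 8.8e-05, 0.0117 and 0.0296), and without replicate 2 the Th1 list higher (8.02e-11). Cholesterol synthesis genes did not pass either (camera adjusted p = 0.857).

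Markers of other cells stood higher in Foxp3-KO as lists: innate-like T cells (3 of 16 were higher and 1 lower, 7 and 2 adjusted over the list alone (median 1.41, or 1.06 with undetected members at bound, camera adjusted p = 0.0101, adjusted p = 0.617 with an estimated correlation)), myeloid cells (0 of 23 were higher and 0 lower, 0 and 0 adjusted over the list alone (median 1.30, camera adjusted p = 0.0047, adjusted p = 0.887 with an estimated correlation)) and B cells (0 of 11 were higher and 0 lower, 0 and 0 adjusted over the list alone (median 2.39, or 1.02 with undetected members at bound, camera adjusted p = 0.0129, adjusted p = 0.887 with an estimated correlation)). Klrb1c (5.07 ± 0.96) was the NK receptor gene called among them. Without Foxp3-KO replicate 1 these 3 calls ended, at adjusted p of 0.330, 0.466 and 0.398, and the B cell call also ended without WT Treg replicate 2 (0.0689) and with only probes above background on all arrays (0.140). Without Foxp3-KO replicate 2 the calls of interferon genes (0.205), maturation genes (0.168) and migration receptors (0.904) ended, the last also without WT Treg replicate 2 (0.0696). Fry called 6 lists, and the 14 lists without a camera call had adjusted p of 0.189 to 0.857. The gene count rested on the pooled spread: limma on these 4 arrays alone called 0 genes, with 2287 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0651, array weights by group gave 301, an intensity trend 1304 and no filter on dim probes 400. Without Foxp3-KO replicate 1 it was 1342, with 591 higher and 751 lower, and 4 lists were higher and 9 lower, from 7 and 5. It was 296 and 71 without WT Treg replicate 1 or 2, and 215 without either WT Tconv replicate, and of the 47 genes named here 10 kept their calls without each array in turn (Aurka, Ccnb1, Ccr10, Cdk1, Cox6a2, Foxp3, Gpr83, Rrm2, Upb1 and Zbtb16).

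Nr4a-TKO against Foxp3-KO precursors sets groups with different sort gates side by side. Type 2 cytokine genes were higher on the arrays labelled Nr4a-TKO, Il13 by 227-fold and Il4 by 33.1-fold. Regulatory T cell genes, Th17 genes and proliferation genes were higher there too, and interferon response, immature thymocyte and conventional T cell genes were lower, as lists. With an estimated correlation no list call was left here (adjusted p = 0.432 to 0.653). The comparison called 4558 genes, 2435 higher and 2123 lower, with 1616 at least 2-fold (999 higher and 617 lower). With median scaling 2759 were higher and 1375 lower. After Il13 (7.82 ± 0.10) the leading increases were in Gzmb (6.09 ± 0.97), Ltb4r1 (6.07 ± 0.84), Jcad (6.02 ± 0.45), the IL-33 receptor Il1rl1 (5.95 ± 1.21) and the IL-1 decoy receptor Il1r2 (5.42 ± 0.66). Ccl4 (5.32 ± 1.20), the carboxypeptidase Cpe (5.18 ± 0.85), Srxn1 (5.17 ± 0.68) and Il4 (5.05 ± 0.42) followed, with adjusted p of 1.59e-05 to 0.0236. Undetected in Foxp3-KO, Calca was at least 233-fold higher, Il5 at least 71.1-fold and the collagen gene Col18a1 at least 41.8-fold. The leading decreases were in Arhgap20 (-5.96 ± 0.20), Slc22a2 (-5.52 ± 0.17), Pyroxd2 (-5.17 ± 0.44), the NK receptor Klra8 (-3.65 ± 0.81), Lypd6b (-3.55 ± 0.58), Gsta4 (-3.44 ± 0.12), Cybrd1 (-3.42 ± 0.21), Rasl11b (-3.36 ± 0.18), Slc16a5 (-3.33 ± 0.30) and Selp (-3.31 ± 0.19). Lad1, Pla2g4f and C1ql3 were undetected on the arrays labelled Nr4a-TKO and at least 94.5-fold, at least 31.2-fold and at least 22.1-fold lower.

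Th2 genes were higher. Of 22 genes 17 were higher and 0 lower, 17 and 0 adjusted over the list alone (median 2.94, or 2.50 with undetected members at bound, camera adjusted p = 5.56e-06, adjusted p = 0.432 with an estimated correlation). The EGF family ligand Areg (6.12 ± 0.77) was called. For Th17 genes 9 of 13 were higher and 0 lower, 10 and 0 adjusted over the list alone (median 1.26, camera adjusted p = 0.000132, adjusted p = 0.515 with an estimated correlation). Batf (2.18 ± 0.18) and Rora (1.17 ± 0.14) were among them. For Th1 genes 6 of 23 were higher and 1 lower, 6 and 1 adjusted over the list alone (median 1.65, camera adjusted p = 0.0174, adjusted p = 0.653 with an estimated correlation). The regulatory T cell list was higher there. Of 36 genes 22 were higher and 4 lower, 24 and 5 adjusted over the list alone (median 1.98, camera adjusted p = 0.000192, adjusted p = 0.584 with an estimated correlation). Icos (2.11 ± 0.13), Izumo1r (1.35 ± 0.09), Ctla4 (3.15 ± 0.34) and Foxp3 (1.67 ± 0.24) were higher and Ikzf4 (-2.29 ± 0.17) was lower. Proliferation genes (19 of 37 were higher and 1 lower, 23 and 1 adjusted over the list alone (median 0.34, camera adjusted p = 8.24e-05, adjusted p = 0.490 with an estimated correlation)), with Tk1 (0.99 ± 0.09) and Mcm5 (0.71 ± 0.10), and glycolysis genes (13 of 20 were higher and 4 lower, 13 and 4 adjusted over the list alone (median 0.45, camera adjusted p = 0.0104, adjusted p = 0.432 with an estimated correlation)), with Aldoa (1.09 ± 0.09) and Slc2a1 (0.98 ± 0.08), were higher. For IL-2 and STAT5 genes 11 of 20 were higher and 3 lower, 11 and 4 adjusted over the list alone (median 0.63, camera adjusted p = 0.0174, adjusted p = 0.432 with an estimated correlation). Tnfrsf8 (at least 2.90-fold higher), Cish (1.21 ± 0.11) and Socs3 (2.86 ± 0.30) were members. For co-inhibitory receptor genes 13 of 22 were higher and 5 lower, 15 and 5 adjusted over the list alone (median 1.11, camera adjusted p = 0.019, adjusted p = 0.584 with an estimated correlation). Btla (0.79 ± 0.08) and Vsir (1.42 ± 0.14) were higher and Tox (-0.78 ± 0.07) was lower. B cell markers (0 of 11 were higher and 0 lower, 0 and 0 adjusted over the list alone (median 1.61, camera adjusted p = 0.101, adjusted p = 0.741 with an estimated correlation)) and myeloid markers (0 of 23 were higher and 1 lower, 0 and 0 adjusted over the list alone (median 0.50, camera adjusted p = 0.467, adjusted p = 0.895 with an estimated correlation)) did not pass. The B cell list was called higher in 5 of 20 other settings, without the filter on dim probes (adjusted p = 0.0019), with the replicate block (0.0273), and without Nr4a-TKO replicate 2 (0.0018), Foxp3-KO replicate 1 (0.0271) or both, where the myeloid list was called too (5.46e-05 and 0.0254).

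Interferon response genes were lower. Of 28 genes 15 were lower and 3 higher, 20 and 3 adjusted over the list alone (median -0.60, camera adjusted p = 2.39e-05, adjusted p = 0.432 with an estimated correlation). Oasl2 (-1.98 ± 0.11), Ifit2 (-1.28 ± 0.10) and Rtp4 (-0.86 ± 0.09) were examples. Immature thymocyte genes were lower. Of 26 genes 16 were lower and 2 higher, 18 and 3 adjusted over the list alone (median -0.97, camera adjusted p = 0.000192, adjusted p = 0.501 with an estimated correlation). Cd1d1 (-1.06 ± 0.12) and Dntt (-2.59 ± 0.36) were called. Genes of conventional T cells were lower. Of 20 genes 13 were lower and 1 higher, 15 and 2 adjusted over the list alone (median -1.11, camera adjusted p = 0.000192, adjusted p = 0.501 with an estimated correlation). Tgfbr3 (-2.19 ± 0.23), Klf3 (-1.15 ± 0.12) and the repressor of effector programs Bach2 (-1.41 ± 0.19) were among them. S1pr1 (-1.73 ± 0.06) and Klf2 (-0.82 ± 0.07) were lower within the maturation list, which did not pass (9 of 23 were lower and 4 higher, 9 and 7 adjusted over the list alone (median -0.24, camera adjusted p = 0.122, adjusted p = 0.584 with an estimated correlation)). Weaker calls were those of TNF receptor and NF-kB genes (9 of 26 were higher and 3 lower, 10 and 3 adjusted over the list alone (median 0.27, camera adjusted p = 0.0223, adjusted p = 0.432 with an estimated correlation)), follicular helper genes (7 of 18 were higher and 2 lower, 8 and 2 adjusted over the list alone (median 1.03, camera adjusted p = 0.0215, adjusted p = 0.584 with an estimated correlation)) and early response genes (13 of 30 were higher and 3 lower, 13 and 3 adjusted over the list alone (median 0.52, camera adjusted p = 0.0414, adjusted p = 0.555 with an estimated correlation)). The TNF receptor call ended without Nr4a-TKO replicate 1 (adjusted p = 0.0631) or Foxp3-KO replicate 1 (0.0560), the follicular call without Nr4a-TKO replicate 1 (0.0961) or Foxp3-KO replicate 2 (0.0525), and the early response call without Nr4a-TKO replicate 2 (0.0546) or Foxp3-KO replicate 1 (0.050, just above the threshold). The early response call also ended with median scaling (adjusted p = 0.0627), the TNF receptor call with quantile normalization (0.0573), the co-inhibitory receptor call with only probes above background on all arrays (0.0987), and the glycolysis call without Nr4a-TKO replicate 2 and Foxp3-KO replicate 1 together (0.0596). The 12 lists without a call had camera adjusted p of 0.0706 to 0.932, and fry called 16. The count of genes was 894 in a fit of these groups alone, which kept 869 of the 4558 calls. The count was 2753 with array weights by group and 7371, of which 5030 were lower, without the filter on dim probes. It was 2027 and 2664 without Nr4a-TKO replicate 1 or 2 and 2927 without either WT Tconv replicate, and Ccl4, Gzmb, Il1rl1 and Klra8 lost their calls without some array.

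Next, the WT Treg to WT Tconv difference shared by each precursor group was counted. Of the 1867 genes higher in WT Treg, 1236 (66.2%) were also higher than in WT Tconv on the arrays labelled Nr4a-TKO and 1059 (56.7%) in Foxp3-KO. Of the 2907 lower genes, 1600 (55.0%) were also lower in Nr4a-TKO and 1421 (48.9%) in Foxp3-KO. Genes called in opposite directions numbered 221 for Nr4a-TKO and 21 for Foxp3-KO. Independent gene lists of these sizes would share 400 and 779 genes with Nr4a-TKO, and 194 and 415 with Foxp3-KO. Both comparisons used the same WT Tconv arrays, so part of the excess may come from these, and splitting them would leave 1 to each. WT Treg and Foxp3-KO also shared a slide row without WT Tconv, which may add to the excess of Foxp3-KO. The rows lay apart on the second component (21.9% of variance). In 100 simulations sharing WT Tconv, with no real effects and so few calls, shared calls had a median of 0 and maximum of 1. Across the 13498 genes, which are not independent replicates, the WT Treg difference correlated with that of Nr4a-TKO at r = 0.694 and with that of Foxp3-KO at r = 0.806, against 0.504 and 0.499 in these simulations, with covariances of 1.01 and 0.77 against 0.04 in each. The shared counts fell to 875 and 931 for Nr4a-TKO and to 403 and 424 for Foxp3-KO without WT Tconv replicate 1 or 2, from 2836 and 2480. Without the filter on dim probes Foxp3-KO shared 1492. The order of the groups was not stable: median scaling gave 3381 for Nr4a-TKO and 3674 for Foxp3-KO, with 2334 and 2850 of 4234 lower genes, and leaving out Nr4a-TKO replicate 1 gave 1932 and 2114.

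The precursor groups were also compared directly over these gene sets, which the WT Tconv arrays help to define. Genes higher in WT Treg had a mean log2 difference of 0.33 between Nr4a-TKO and Foxp3-KO, with 618 higher and 430 lower, and camera did not separate them from other genes (p = 0.101, or 0.537 with an estimated correlation). Genes lower in WT Treg had a mean of -0.03, with 519 higher and 486 lower (camera p = 0.898, or 0.949 with an estimated correlation). The shift, the first mean minus the second, was 0.36. It rose to 0.93, with a camera p of 0.0475 for the weaker set, once Nr4a-TKO replicate 2 and Foxp3-KO replicate 1 were left out, a choice made after the data were seen. It was 0.77, at a camera p of 0.165, without Foxp3-KO replicate 1, 0.10 and 0.14 without WT Tconv replicate 1 or 2, 0.22 and 0.20 without WT Treg replicate 1 or 2, and 0.21 without Nr4a-TKO replicate 1.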

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

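All tests of explanations in this part were chosen after the results were seen. Against WT Treg, 75 genes were called in opposite directions in the 2 precursor groups with the difference between the groups also called, and the laminin chain Lama5 was among them (2.48 ± 0.34 in Nr4a-TKO and -2.33 ± 0.34 in Foxp3-KO). Against WT Tconv there were 140 such genes, including Il13 (5.20 ± 0.10 and -2.62 ± 0.10) and Il4 (2.85 ± 0.42 and -2.20 ± 0.42). Outside the gene tests, 11882 probes without a gene symbol were bright enough to test. Against WT Tconv, 930 of them were higher and 1314 lower in WT Treg. In Nr4a-TKO 1229 were higher and 3139 lower, and in Foxp3-KO 653 and 1013.

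The helper cytokine genes are the pattern to follow up: 33 members of the Th1, Th2 and Th17 lists were higher on the arrays labelled Nr4a-TKO than in WT Treg. B or myeloid cells stay open as a cause, as a replicate pair per group cannot decide it and the groups went opposite ways. On the Nr4a-TKO arrays 40 members at least 2-fold higher, called or not, differed less between replicates than the marker lists. Medians differed by -1.84 for B cell and -0.42 for myeloid markers (95% bootstrap intervals over genes -2.09 to -1.53 and -0.74 to -0.25). Of the 40, 34 were higher in replicate 1 there (median 0.18, random lists -0.09 to 0.10). In Foxp3-KO 38 were, by more than either marker list (2.24 against 1.39 and 0.92). The 9 of 9 list calls kept under 3 other scalings and background corrections do not decide scaling. Camera compares a list with other genes, so array-wide shifts move both alike. The Th17 call ended with only probes above background on all arrays (adjusted p = 0.0856). Effector or returning T cells inside the Nr4a-TKO gate cannot be told apart from a change within precursors. Such cells might lower immature thymocyte genes, whose median was -0.48 against WT Treg (camera adjusted p = 0.340). Against Foxp3-KO it was -0.97 (adjusted p = 0.000192, or 0.501 with an estimated correlation). Maturation and exit genes were lower than in WT Treg (median -0.67, adjusted p = 0.0134, or 0.698 with an estimated correlation), which maturation of the precursors would not give. The genotype, the biological explanation that the design names, stays open and untested, because no wild-type precursors were sorted with that gate.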

How the results depend on the processing

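Array weights by group and the joint removal of Nr4a-TKO replicate 2 and Foxp3-KO replicate 1 were chosen after the data were seen. Signal over background limits what dim genes can show. Of 315 values of the counts, overlaps and shift under other settings, 252 stayed within 1.5 times or on the same side of the threshold. Of 5472 values of 288 single-gene differences, 0 called differences turned direction, 381 lost their call and 1 gained it, and 221 differences kept their side of the threshold without each array in turn. Where a count changed below, the cause was not tested unless fewer arrays or other units of testing give it.

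With a 2-fold minimum the gene counts were 1630, 2626, 1087, 1760, 375 and 1616, in the order WT Treg, Nr4a-TKO and Foxp3-KO against WT Tconv, Nr4a-TKO and Foxp3-KO against WT Treg, and Nr4a-TKO against Foxp3-KO. With every probe as a unit they were 7439, 12236 and 5065 against WT Tconv, 8610 for Nr4a-TKO against WT Treg and 8614 for the precursors. Median scaling, which moved the median of all genes in Foxp3-KO against WT Tconv from -0.10 to -0.25, gave 5026 there. Without the filter on dim probes, Foxp3-KO against WT Tconv had 2146 genes, 7 lists and 1492 shared genes, Foxp3-KO against WT Treg 400 genes and the precursors 7371. An intensity trend gave 1304 for Foxp3-KO against WT Treg. Fits of only the groups compared gave 1285 for Foxp3-KO against WT Tconv, 894 for the precursors and 0 for Foxp3-KO against WT Treg. They gave 6006 for WT Treg and 6802 for Nr4a-TKO against WT Tconv, from 4774 and 6511. Array weights by group gave 301 for Foxp3-KO against WT Treg and 2753 for the precursors. The joint removal gave a shift of 0.93. Without the filter on dim probes the shift was 0.26 at a camera p of 0.00116, but both gene sets moved the same way against other genes, so it was not called. With an estimated correlation, camera called 1 list in WT Treg against WT Tconv and 0 in each other comparison, where fry called 18, 14, 9, 6 and 16.

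Leaving out arrays, the joint removal included, gave 1654 to 6006 genes for WT Treg against WT Tconv, 3080 to 7182 for Nr4a-TKO and 470 to 4141 for Foxp3-KO against WT Tconv, 2121 to 5837 for Nr4a-TKO and 71 to 1498 for Foxp3-KO against WT Treg, and 2027 to 5336 for the precursors. The lone array of a group was then assumed to vary like the other groups. Shared genes ranged from 875 to 3579 for Nr4a-TKO and from 403 to 3063 for Foxp3-KO, and the shift from 0.10 to 0.93. Replicate differences correlated at 0.15, 0.19 and 0.26 among WT Treg, Nr4a-TKO and Foxp3-KO and at -0.03 to -0.01 with WT Tconv. As not all groups deviated together and the labels name nothing that the numbers share, the block on replicate number is an alternative. It gave 4483, 6209, 2937, 4487, 605 and 4149 genes, and with it the early response call between the precursor groups (adjusted p = 0.0675) and the survival call in Nr4a-TKO against WT Tconv (0.0591) were not made, while those of B cell markers between the precursor groups (0.0273) and of pro-apoptotic (higher) and conventional T cell genes (lower) in WT Treg against WT Tconv (both 0.0485) were gained. No called list turned direction in any of 20 settings.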

Other observations

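The tests of explanations in this part were all chosen after the results were seen. Pro-apoptotic genes did not pass as a list between Nr4a-TKO and Foxp3-KO: 9 of 21 were higher and 5 lower, 9 and 5 adjusted over the list alone (median log2 difference 0.30, camera adjusted p = 0.427, adjusted p = 0.584 with an estimated correlation), and were called higher without the filter on dim probes (adjusted p = 0.0496). The death receptor gene Fas was lower on the arrays labelled Nr4a-TKO (-1.26 ± 0.10). Pmaip1, which encodes the BH3 protein Noxa, was higher than in WT Tconv in WT Treg (4.34 ± 0.35), Nr4a-TKO (6.0 ± 0.35) and Foxp3-KO (3.98 ± 0.35). Xist, the X-inactivation RNA, was above background on Nr4a-TKO replicate 2 alone, at a log2 signal of 1.31, against -6.39 on replicate 1, and the Y-linked Ddx3y was at 1.25 there against 2.37 on replicate 1. Eif2s3y was at 2.31 and 3.48 on those arrays. The sex-linked list had 4 tested genes (Uty, Eif2s3y, Ddx3y and Kdm5d), too few for a list test.

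B cell and myeloid markers were higher in both precursor groups than in WT Tconv, and H2-Ab1 lay at a log2 signal of 7.16 and 6.60 on the Nr4a-TKO arrays, 6.51 and 6.05 on Foxp3-KO, 5.70 and 4.0 on WT Treg, and 2.49 and 2.58 on WT Tconv. Other cells carried through the sort are a candidate explanation, because replicates of the same gate differed. From replicate 2 to replicate 1 B cell markers rose by a median of 2.02 in Nr4a-TKO and 1.39 in Foxp3-KO (11 of 11 genes each). Myeloid markers rose by 0.60 (19 of 23) and 0.92 (23 of 23). Random lists of like brightness gave -0.20 to 0.20 for the B cell list in Nr4a-TKO. A CD4 single-positive gate would remove B cells and most myeloid cells, 6 of 11 and 16 of 23 of these markers were above background in WT Tconv, and 0 and 1 are also in another list. The 12 of 12 list calls kept under 3 other scalings and background corrections do not decide scaling, as camera cannot see array-wide shifts. Expression of these genes by the T cells was not tested.

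Foxp3-KO replicate 1 lay toward the arrays labelled Nr4a-TKO, away from replicate 2. More B and myeloid cells in replicate 1 may account for part of it, as their markers were higher there by medians of 1.39 and 0.92 and lay higher still or between the replicates on the Nr4a-TKO arrays, at medians over WT Tconv of 4.91 and 2.77 for B cells, against 3.27 and 1.78 on Foxp3-KO. Innate-like T cell markers were also higher in replicate 1, by 1.1, but lay at -0.28 and -0.35 on the Nr4a-TKO arrays, so by themselves they carry it away from Nr4a-TKO, and 8 of the 16 genes are in another list and 15 of 16 above background in WT Tconv. The 40 helper members, chosen for being high in Nr4a-TKO, were higher in replicate 1 by more than those markers, at 2.24 (38 of 40), and the replicates lay at 2.77 and 1.51 for regulatory T cell genes and 1.81 and 0.13 for Th17 genes, so what drives the position stays open. No biological explanation was tested.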
